A study of Mus musculus with 8 samples.

How the data were processed

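Dorsal root ganglia, which hold the cell bodies of the sensory neurons of the body, were taken from C57BL/6 mice aged 21 to 30 days, and the ganglia of 4 mice were pooled for each sample, per the labels' protocols. After dissociation, living cells were kept for 30 min with an antibody to the proteasome subunit β5, the product of Psmb5, and for 40 min with a fluorescent secondary antibody. An antibody applied to living cells reaches epitopes at the cell surface, and the labelled cells were called positive for the neuronal membrane proteasome (NMP), a form of the 20S proteasome exposed at the plasma membrane of neurons. Flow cytometry separated NMP-positive from NMP-negative cells, which were then used for droplet single-cell RNA sequencing with 3′ end counting. The extraction protocol names a procedure for isolating nuclei. Whether whole cells or nuclei entered the droplets is not given in the sources used here.

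The labels list 8 samples, 4 NMP-positive and 4 NMP-negative. Their descriptions name 4 sequencing lanes of 1 library for each population, so each population was taken as 1 library with no biological replicate. The values came from 1 table of cluster markers covering 20 clusters named by the authors. Its columns hold no sample, so no value could be assigned to either sorted population.

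Per the file headers, the authors' deposited table gives a p-value for each gene and cluster, an adjusted p-value, an average log2 fold change of the cluster against all other cells, and the fraction of cells with the gene detected in the cluster and in the other cells. The submitters' processing notes name Seurat. The aligner, genome build, annotation, filters on cells, normalization, clustering settings and treatment of doublets are not given in the sources used here. The table holds 56694 pairs of gene and cluster over 9229 genes. No deposited p-value exceeds 0.01, no absolute log2 fold change is below 0.25, and in every pair at least 1 of both fractions reaches 10%. The deposited adjusted p-value equals the p-value times 32285 in all 50216 pairs in which this could be checked. A gene missing for a cluster can therefore have been close to the other cells in level, or too rare, and was not read as absent.

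The p-values treat cells as the units of the test, and the clusters had been defined from the same expression values. They were used only as a filter. A gene was called higher or lower in a cluster at an adjusted p under 0.05, by the sign of its log2 fold change, and "higher" or "lower" below always refers to that filter against all other cells. No depth per cell and no number of cells is given, so no confidence interval was attached to any fraction of cells, and fractions are printed as percentages.

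The share of all cells that each cluster holds follows from the table. For a gene, the overall share of cells with its transcript is the share in the other cells plus the cluster's weight times the difference between the cluster and the other cells, and this overall share is the same whichever cluster is used. The weights were solved by least squares over 6748 genes with a difference of at least 5 percentage points, with 200 bootstrap draws over genes. The residual was 0.0256 percentage points, against 0.0289 expected from the rounding of the deposited fractions alone.

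A set of 37 gene lists, 19 of cell types and 18 of functions, was fixed before the data were examined. The lists hold 365 genes, of which 314 occur in the table and 51 belong to more than 1 list. For each list and cluster, a one-sided Fisher's exact test compared the list with the genes higher in the cluster by a log2 fold change of at least 0.5 and present in at least 25% of its cells, against a background of all 9229 genes. Benjamini-Hochberg adjustment ran over all 740 pairs of list and cluster. Genes are not independent replicates, so these p-values describe the overlap of lists. Counts of higher members printed beside them use the adjusted p filter alone and can exceed the number of members that the exact test counted. The median log2 fold change of the listed members was placed among 10000 random lists of the same size drawn from the genes given for that cluster and matched on the share of other cells in 10 bins, where at least 3 members were listed. Counts adjusted over the list alone used the deposited p-values of its members, with 1 for a member not listed. Overlaps between clusters were given as shared genes in percent of the genes higher in either, with the same thresholds.

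The genes named were chosen by a rule fixed before the data were examined. For each cluster it takes the 3 genes of largest log2 fold change among those higher, present in at least 25% of its cells and at least 20 percentage points more frequent than in other cells, leaving out predicted genes. It adds up to 4 members of each list called in a cluster, the proteasome genes of largest and smallest fold change, and Psmb5, Gpm6a, Gpm6b, Mrgpra3, Mrgprd, Cysltr2, Sst, Th, Trpv1, Calca, Nefh and Trpm8. Other values of Calca, Tac1 and Psmb5, the further members of the 20S core, and Apoe, Sparc, Glul, Ptprz1, Cdh19, Mrgprb4, Fos, Egr1, Malat1, Gap43, S100a8, S100a9 and the Fc receptor genes were singled out after their values had been seen. Mrgpra3, Mrgpra2b, Mrgprb4 and Mrgprx1 belong to a family of similar genes, and how 3′ reads were divided among them is uncertain. The table gives gene symbols with no position and no build, so no coordinates are printed.

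The procedures were tested on simulated tables of 9229 genes. Planted cluster shares were recovered within 0.00474 percentage points. With the gene names shuffled, 1 of 740 pairs of list and cluster was called, and 5.31% of the pairs lay outside the central 95% of the random lists. Of 20 planted lists with 7 of 14 genes among the higher genes, 19 were recovered. Alternatives fixed beforehand varied the adjusted p, the fold change and the share of cells required, the background of the list test, the summary of a list, the solution for the cluster shares and the ranking of named genes. A condition that the share of cells differ in the direction of the fold change was added after the data had been seen. The alternatives that needed values per sample could not be run. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.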

Results

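Single-cell RNA sequencing was applied to mouse dorsal root ganglion cells sorted by surface labelling for the proteasome subunit β5 into an NMP-positive and an NMP-negative population. The labels list 4 samples per population, which are sequencing lanes of 1 library each, so there were no replicates. The available values describe 20 clusters of cells, each compared with all other cells, without their population of origin. Which genes differed between NMP-positive and NMP-negative cells could therefore not be compared. Both clusters whose names end in 488p, Peptidergic 488p and Unknown 488p, (written here with a space) carry a suffix that resembles the wording of the NMP-positive labels, but its meaning is not stated.

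The cells fell into 3 broad groups by the names given to them. The 10 named neuron clusters held 40.8% of all cells, the 3 clusters named Low.UMI (few transcript molecules per cell) held 28.6% and the 7 clusters named Unknown held 30.7%. The largest single clusters were Low.UMI.Pep with 14.1%, Low.UMI.Nonpep with 11.6%, Unknown.1 with 9.17% and Unknown.2 with 8.98%. Among the named neuron clusters, the 4 CGRP clusters together held 17.2%, SST 5.86%, Non-peptidergic 5.24%, Cold.sen 4.38% and LTMR 3.93%. Peptidergic 488p held 2.94% and Unknown 488p 1.86%. The 20 shares were solved separately and summed to 100.01%, and the largest bootstrap SD over genes was 0.00367 percentage points. This spread covers the rounding of the fractions, not the variation between mice or libraries.

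**Figure D1:**
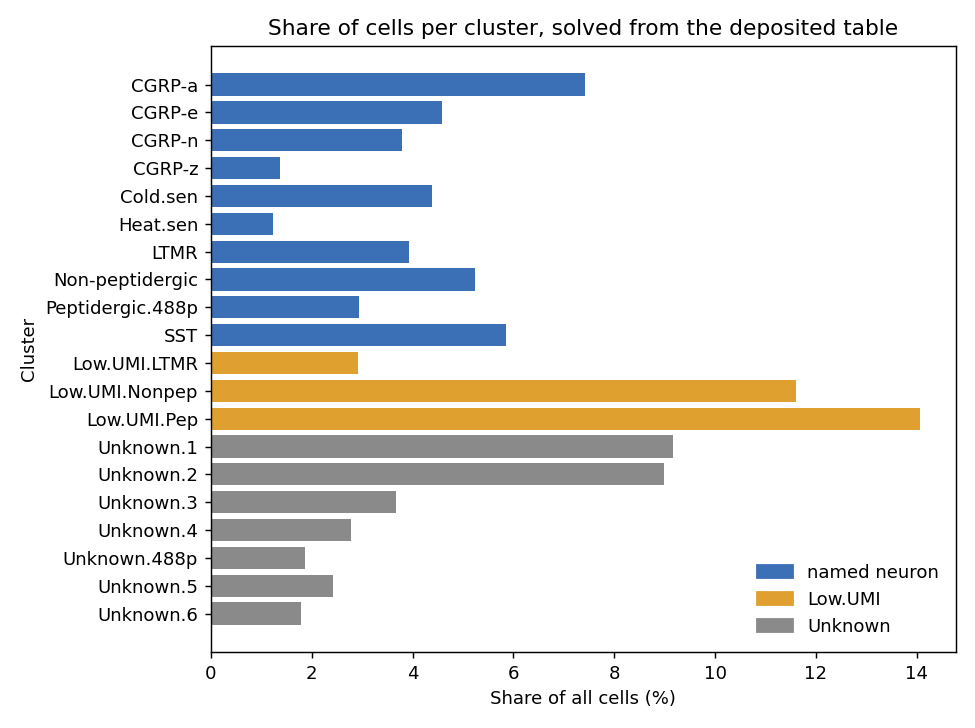
Share of all cells (%) held by each of the 20 clusters, solved from the deposited fractions of cells; bars start at 0 and are coloured by the kind of cluster name. Low.UMI.Pep is the longest bar with 14.1%, and the 7 Unknown clusters add up to 30.7%.

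Which cell types the unnamed clusters contained was addressed with the fixed lists. Here and below, counts of higher members use the adjusted p filter alone. The exact test counted only members that also reached its minimum fold change and share of cells, in some lists fewer. Each of the 7 Unknown clusters had a called list of a non-neuronal cell type of the ganglion, and Unknown.4 had 2. Unknown.1 was endothelial-like, with 8 of 8 markers of vessel-lining cells higher (Fisher's exact test, adjusted p = 2.75e-06). Its leading genes in the authors' deposited table were Flt1, a receptor for vascular growth factors (log2 fold change 4.98, in 99.0% of its cells and 2.1% of other cells), Ly6c1 (4.14) and the tight junction gene Cldn5 (4.00). Unknown.2 was satellite-glia-like, with 10 of 10 markers of the glia that wrap sensory cell bodies higher (exact test, adjusted p = 2.54e-09). The authors' deposited table gave log2 fold changes of 6.07 for the lipid carrier gene Apoe, 6.02 for the fatty acid binding protein gene Fabp7 and 4.67 for Dbi.

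Unknown.3 was mural-like, with 7 of 7 measured markers of contractile vessel cells higher (exact test, adjusted p = 1.06e-05), led in the authors' deposited table by Acta2 (6.42), Tagln (5.88) and Tpm2 (5.32). Unknown.4 was Schwann-cell-like, with 9 of 10 markers of myelinating glia higher and 1 lower (exact test, adjusted p = 5.42e-11). The myelin gene Mbp (5.02) and Ncmap (4.23) were among its higher genes in the authors' deposited table. The satellite glia list was also called in Unknown.4 (exact test, adjusted p = 0.0344), with 4 members higher and 3 lower. Unknown.5 and Unknown.6 were both fibroblast-like, with 8 of 8 markers higher in each (exact test, adjusted p = 1.71e-06 and 5.44e-09). Unknown.5 was led in the authors' deposited table by Igfbp6 (5.69), the collagen gene Col3a1 (4.33) and Islr (3.96), and Unknown.6 by Apod (8.19), the proteoglycan gene Dcn (5.73) and Col1a1 (5.15). Both clusters shared 36.2% of the genes higher in either. Unknown.6 also had a called list of myelinated A-fibre neuron genes (exact test, adjusted p = 0.0313), through Spp1, Ntrk3, Etv1 and Ntrk2, which code for a secreted matrix protein, neurotrophin receptors and a transcription factor. That call and the satellite glia call in Unknown.4 were lost against the genes listed for the cluster itself (exact test, adjusted p = 0.0700 and 0.351) and at a log2 fold change of at least 1 (0.444 and 0.224).

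Transcripts of neuropeptide genes were found in all of these non-neuronal clusters. Calca, the gene of the pain-related peptide CGRP, was detected in 34.2 to 61.0% of the cells of the 7 Unknown clusters in the authors' deposited table, and Tac1, the gene of substance P, in 31.5 to 47.2%. Their log2 fold changes there were below 0 in each of the 7 clusters in the authors' deposited table, from -4.00 to -2.94 for Calca and from -3.59 to -2.65 for Tac1. What brought these transcripts into the clusters was not measured.

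Of the 10 named neuron clusters, the 4 CGRP clusters, SST, LTMR, Non-peptidergic and Cold.sen carried a list of the sensory neuron class that their names point to. Heat.sen had no cell type list called, and Peptidergic 488p had lists of non-peptidergic neurons called in place of peptidergic ones. SST cells had all 10 of 10 genes of the Sst and Nppb itch neurons higher (exact test, adjusted p = 4.50e-11). Among these the authors' deposited table gave Nppb (log2 fold change 4.11, in 99.6% of SST cells and 1.7% of other cells), the itch cytokine receptor gene Il31ra (3.78), its signalling kinase gene Jak1 (3.49) and the somatostatin gene Sst (3.43). The list of itch receptors was called in SST as well (exact test, adjusted p = 0.0138), with 7 of 16 measured members higher, among them Htr1f (3.34) and the leukotriene receptor gene Cysltr2 (2.41) in the authors' deposited table. The neuropeptide list was called in SST through Nppb, Sst, Nts (3.16 in the authors' deposited table) and Bdnf (exact test, adjusted p = 0.0306), while 7 members were lower and the median of the listed members was -1.35. Against the genes listed for SST itself, the itch receptor call (exact test, adjusted p = 0.269) and the neuropeptide call (exact test, adjusted p = 1) were lost.

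LTMR cells had 9 of 9 measured genes of the Th-expressing touch neurons higher (exact test, adjusted p = 2.46e-10). The authors' deposited table gave log2 fold changes of 2.54 for Piezo2, the main mechanically gated channel of touch neurons, 2.43 for Rarres1, 2.21 for Th and 2.19 for Tafa4. Dpp10 (2.95) and Kcnip4 (2.84), both auxiliary subunits of potassium channels, were the genes of largest fold change in LTMR in the authors' deposited table. Non-peptidergic cells had 11 of 11 measured genes of the Mrgprd neurons higher (exact test, adjusted p = 2.59e-13). Mrgprd itself was, in the authors' deposited table, in 97.8% of these cells and 5.6% of other cells (1.43), and the largest fold changes were those of the glutamate receptor gene Grik1 (3.28), Dgki (2.93) and Sgcd (2.35). Cold.sen cells had 5 of 6 genes of the cold-sensing neurons higher (exact test, adjusted p = 0.00151). Trpm8, the cold-activated channel gene (2.76, in 96.8% of cells against 5.8%), Cdh8 (2.35) and Foxp2 (2.18) stood for them in the authors' deposited table, beside Pcdh9 (2.80) and Schip1 (2.66). Genes of myelinated A-fibre neurons were called in Cold.sen too (exact test, adjusted p = 0.0245), with Nefh at 1.23 in the authors' deposited table. Both Cold.sen calls were lost against the genes listed for that cluster (exact test, adjusted p = 0.180 for the cold-sensing list and 0.543 for the A-fibre list).

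Heat.sen cells had the largest fold change of Trpv1, the heat- and capsaicin-gated channel gene, in the authors' deposited table (2.98, in 100% of cells against 36.2%). Their leading genes in the authors' deposited table were Thsd7b (3.71), Kirrel3 (3.51) and the calcium-binding protein gene Calb1 (3.22, in 95.9% of cells against 2.8%), while Calca was at -3.98. The 4 CGRP clusters had the list of unmyelinated peptidergic neurons in common, with 8 of 10 members higher in CGRP-a, 9 in CGRP-e, 9 in CGRP-n and 5 in CGRP-z. In CGRP-z 1 member was lower, and Calca, the gene of CGRP, was not higher (-0.51 in the authors' deposited table, not past the adjusted p filter). The adjusted p of the exact test was 3.06e-06, 1.41e-08, 3.74e-07 and 0.00118, and against the genes listed for CGRP-z the last call was lost (0.334), as was that of CGRP-a at a fold change of at least 1 (0.0663). CGRP-a was led by Ptprd (3.62), Lrp1b (2.45) and Sdk1 (2.35), and CGRP-e by Gpc5 (2.43), Lingo2 (2.27) and Nrg3 (2.10), in the authors' deposited table. CGRP-n was led by Fxyd7 (1.98), Cartpt (1.83) and Trappc3l (1.82), and CGRP-z by Tenm2 (3.75), the acid-sensing channel gene Asic2 (2.96) and Klhl1 (2.62), in the authors' deposited table. CGRP-n was the cluster in which the list of myelinated peptidergic neurons was called (exact test, adjusted p = 2.87e-05), with 6 of 7 measured members higher, among them Nefh (1.23), Kit (0.88) and Bmpr1b (0.83) in the authors' deposited table. CGRP-e and CGRP-n shared 43.4% of the genes higher in either, 200 genes where 11.8 were expected for independent lists. That percentage was the largest of the 190 pairs of clusters, and it was lower at a log2 fold change of at least 1. By number, several other pairs shared more genes, led by Unknown.5 and Unknown.6 (285) and by Cold.sen and Heat.sen (256).

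**Figure D2:**
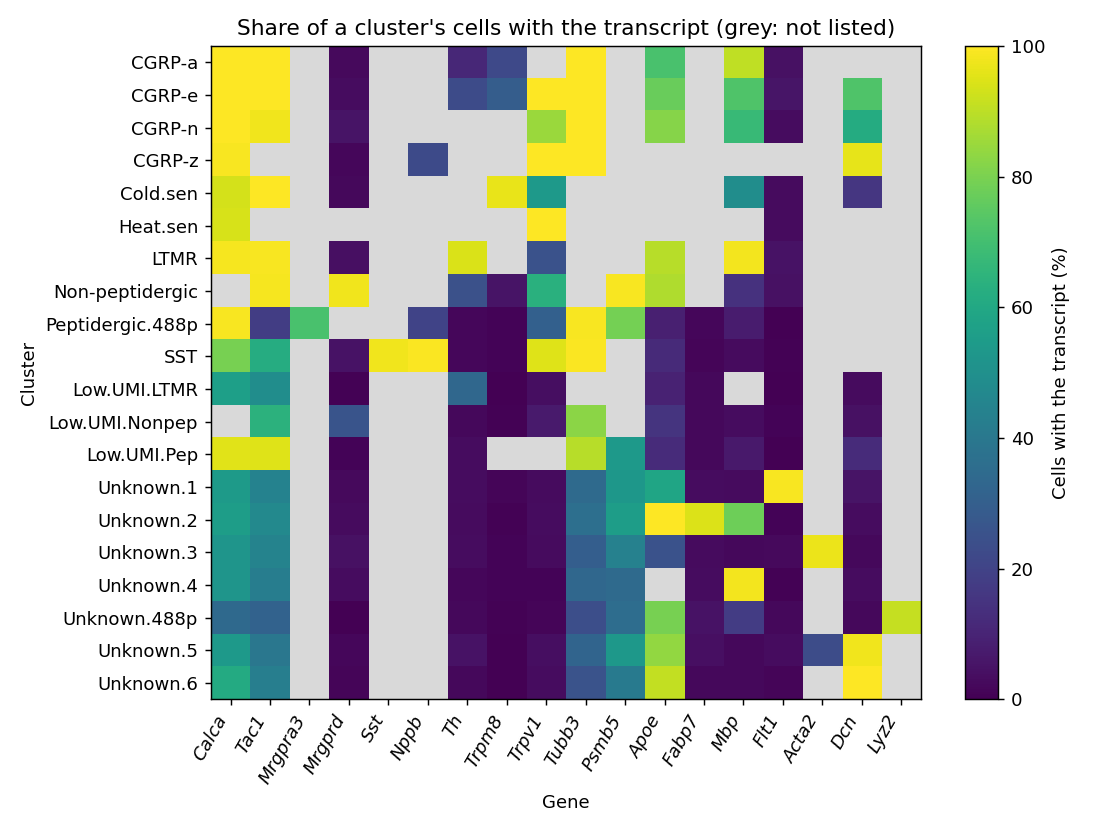
Share of the cells of each cluster (vertical axis) in which the transcript of a gene (horizontal axis) was detected, in percent on the colour scale, as the authors' deposited table gives it; grey marks a gene not listed for that cluster. Apoe is in 71.4% of CGRP-a and 88.1% of Non-peptidergic cells but 11.9% of SST and 8.7% of Peptidergic 488p cells. Its log2 fold changes in CGRP-a and Non-peptidergic are -3.46 and -5.56, neither past the adjusted p filter, against -5.88 in SST and in Peptidergic 488p.

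Lists of neuronal excitability genes were called in several of the neuron clusters, in part through different members. The other cells in each comparison include the Unknown clusters, where Cacna1b was in 1.4 to 2.4% and Scn9a in 2.1 to 5.8% of cells. Not all members were rare there, as Cacna1c was in 86.5% of Unknown.3 cells. These calls may therefore reflect in part neurons set against non-neurons. Voltage-gated calcium channel genes were called in 7 clusters, namely the 4 CGRP clusters, Cold.sen, Heat.sen and LTMR. The counts ranged from 4 of 14 members higher in LTMR to 10 of 14 in Cold.sen. In the authors' deposited table Cacna1e reached 2.42 in CGRP-z, Cacna1d 1.64 in Heat.sen and Cacna2d1, which codes for the subunit bound by gabapentin, 1.58 in CGRP-z. Potassium channel genes were called in CGRP-a, Cold.sen and LTMR, with 7, 6 and 7 of 19 members higher and 2, 4 and 3 lower. Kcnq5 was at 2.31 in CGRP-a and Kcnd3 at 2.25 in LTMR in the authors' deposited table. Sodium channel genes were called in Cold.sen, Heat.sen and LTMR, with 6, 7 and 6 of 11 members higher and 2, 2 and 1 lower. Ionotropic glutamate receptor genes were called in CGRP-a, CGRP-e and Cold.sen, with 4, 5 and 7 of 12 members higher and 2, 1 and 0 lower. The receptor list of neurotrophic factors was called in CGRP-e and CGRP-n, with 4 of 11 members higher in each and 1 and 2 lower. Inhibitory receptor genes were called in CGRP-z through Cnr1, Npy1r, Gabbr2 and Oprm1 (0.57 to 1.22 in the authors' deposited table). Sensory transduction channels were called in Non-peptidergic cells, with P2rx3 at 0.93 in the authors' deposited table, and transcription factors of sensory neurons in LTMR, with 8 of 21 members higher and 5 lower and Pou4f1 at 1.54. Most of these channel and receptor calls depended on the background: against the genes listed for each cluster, of the calcium channel calls those in CGRP-z, Cold.sen, Heat.sen and LTMR were lost, and all of the potassium, sodium, glutamate, neurotrophic, inhibitory and transduction calls. At a log2 fold change of at least 1, the sodium, glutamate, neurotrophic, inhibitory and transcription factor calls were lost, with the potassium calls in Cold.sen and LTMR and the calcium calls in CGRP-n, Cold.sen and LTMR.

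Neuropeptide genes were called in CGRP-a, CGRP-e, CGRP-n and Low.UMI.Pep besides SST, with 5, 8, 6 and 5 of 12 members higher (exact test, adjusted p = 0.00313, 1.16e-07, 3.61e-05 and 4.96e-05). The call in CGRP-a was lost against the genes listed for it (exact test, adjusted p = 0.0505) and at a fold change of at least 0.25 (0.102). General neuronal genes were called in CGRP-n, LTMR and the 3 Low.UMI clusters besides Peptidergic 488p, with 3 to 8 of 10 members higher. At a fold change of at least 1 these calls were lost in CGRP-n, LTMR, Low.UMI.LTMR and Low.UMI.Nonpep (exact test, adjusted p = 0.451, 0.0916, 1 and 1), and that in CGRP-n was also lost against the genes listed for it (0.548). Genes of ubiquitin and proteotoxic stress were called in Low.UMI.Nonpep and Low.UMI.Pep, with 6 and 5 of 15 members higher (exact test, adjusted p = 0.0328 and 0.0318), and both calls ended when a gene also had to be detected in a larger share of cells (0.424 and 0.390) and against the genes listed for each cluster (0.191 and 0.139).

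Each Low.UMI cluster had a called list of the neuron class in its name. Low.UMI.LTMR had 4 of 9 touch neuron genes higher (exact test, adjusted p = 2.04e-05), Low.UMI.Nonpep 8 of 11 Mrgprd neuron genes (exact test, adjusted p = 1.23e-06) and Low.UMI.Pep 6 of 10 peptidergic genes (exact test, adjusted p = 2.01e-05). Of these higher members the exact test counted 4, 6 and 5. Rarres1 (2.91) led Low.UMI.LTMR in the authors' deposited table, Cd55 (2.47) led Low.UMI.Nonpep, and Tac1 (2.51), Calca (2.48) and Scg2 (2.06) led Low.UMI.Pep. Low.UMI.LTMR shared 44 higher genes with LTMR and 41 with Low.UMI.Nonpep, Low.UMI.Nonpep 83 with Non-peptidergic and 96 with Peptidergic 488p, and Low.UMI.Pep 38 with CGRP-e, 49 with Low.UMI.Nonpep and 64 with Peptidergic 488p, numbers that also depend on the length of each list. In the Low.UMI clusters fold change and detection went apart. Of the genes higher in Low.UMI.LTMR, Low.UMI.Nonpep and Low.UMI.Pep, 95.2%, 94.8% and 95.9% were detected in a smaller share of the cluster's cells than of other cells. In the named neuron clusters other than Peptidergic 488p it was the reverse. Of the genes lower in CGRP-n 80.5%, and of those lower in Cold.sen 40.8%, were detected in a larger share. Peptidergic 488p stood apart from both, with 0 of its 651 higher genes and 2 of its 1270 lower genes going against the share of cells.

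**Figure D3:**
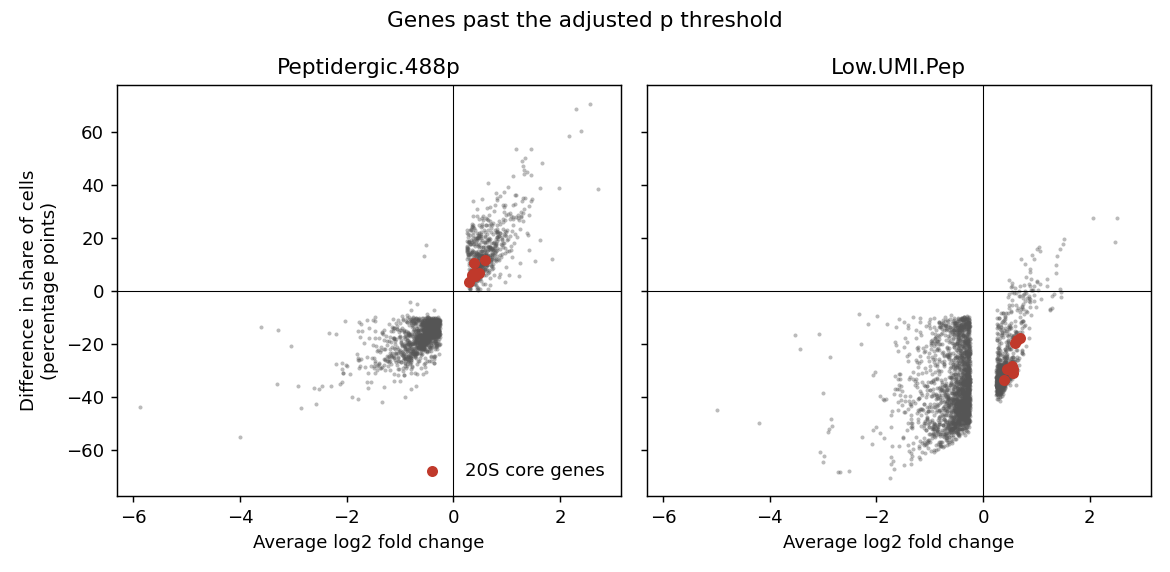
Average log2 fold change (horizontal axis) against the difference in the share of cells with the gene (vertical axis, percentage points) for the genes past the adjusted p threshold in Peptidergic 488p (left) and Low.UMI.Pep (right); each point is a gene, and red points are 20S proteasome core genes. All 7 higher 20S genes of Peptidergic 488p lie above 0 on the vertical axis and all 8 of Low.UMI.Pep below it. This is not particular to the 20S genes, as 0 of the 651 higher genes of Peptidergic 488p and 95.9% of those of Low.UMI.Pep lie below 0.

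Peptidergic 488p combined Calca with genes of itch neurons. Its leading genes in the authors' deposited table were Lxn (log2 fold change 2.71, in 98.3% of its cells and 60.1% of other cells), the itch receptor gene Mrgpra3 (2.57, in 71.4% against 0.9%) and the related Mrgpra2b (2.40, in 79.2% of its cells). The list of Mrgpra3 itch neurons was called, with 3 of 6 measured members higher (exact test, adjusted p = 0.0145), and besides Mrgpra3 the authors' deposited table gave 1.29 for Gfra1 and 0.56 for Mrgprx1. The list of Mrgprd neurons was called as well, with 5 of 11 higher (exact test, adjusted p = 0.00883), of which the test counted 4. Among them were Cd55 (1.31), Plxnc1 (1.06), Scn11a (0.97) and Gna14 (0.81) in the authors' deposited table, but Mrgprd itself was not higher. So was the list of general neuronal genes called (exact test, adjusted p = 0.00632), with Tubb3 at 1.13 in the authors' deposited table. In each of these 3 lists 1 member was lower. Calca was in 99.1% of these cells with a log2 fold change of 0.90 in the authors' deposited table, while Tac1 was in 18.2% of them against 73.3% of other cells (-4.01). Of the unmyelinated peptidergic list, 2 of 10 members were higher and 6 lower, and its median of -0.90 lay at percentile 0.02 of the random lists. Mrgprb4, a marker of touch neurons of the C-fibre class, was in 18.6% of the cells at 0.60 in the authors' deposited table. Peptidergic 488p shared 96 higher genes with Low.UMI.Nonpep where 6.92 were expected (21.9% of the genes higher in either), 95 with SST (12.9%), 91 with Non-peptidergic (14.4%) and 64 with Low.UMI.Pep (13.7%). Against the genes listed for Peptidergic 488p itself the 3 calls were lost (exact test, adjusted p = 0.109 for the Mrgpra3 list, 0.0977 for the Mrgprd list and 0.0526 for the neuronal list). The Mrgpra3 call was also lost at a log2 fold change of at least 0.25.

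Unknown 488p was macrophage-like. All 9 of 9 macrophage markers were higher (exact test, adjusted p = 5.44e-09), and all 10 of 10 general neuronal genes had a fold change below 0, of which 9 were lower. The leading genes, by the authors' deposited table, were the chemokine gene Cxcl2 (6.02, in 80.1% of cells against 1.6%), the lysozyme gene Lyz2 (5.84, in 91.1% against 1.4%) and the antigen presentation gene Cd74 (5.72, in 48.6% against 1.5%). The complement genes C1qb (4.88) and C1qa (4.85) were also higher in the authors' deposited table. The list of ubiquitin and proteotoxic stress genes was called (exact test, adjusted p = 0.0348) with 5 of 15 members higher and 6 lower and a median of -0.36, led by Nfe2l2 (1.53 in the authors' deposited table), a regulator of the oxidative stress response. That call was lost at a log2 fold change of at least 1 (exact test, adjusted p = 0.832), with no minimum share of cells (0.0756) and against the genes listed for the cluster (0.270).

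Because the sort used an antibody to a proteasome subunit, the transcripts of the proteasome were examined in every cluster. Genes of the 20S core, the proteolytic barrel, were higher in several neuron clusters and lower in all 7 Unknown clusters. Of the 14 core genes, 8 were higher in Low.UMI.Pep, 8 in Low.UMI.Nonpep, 7 in Peptidergic 488p, 7 in SST, 3 in Non-peptidergic, 2 in LTMR and 1 in Low.UMI.LTMR, and 0 in the 4 CGRP clusters, Cold.sen and Heat.sen. Adjusted over the list alone, the counts were 12, 9, 11, 7, 3, 2 and 6 in the same order. At an adjusted p under 1e-10, only 0 were left in Low.UMI.Pep, 3 in Low.UMI.Nonpep and 1 in Peptidergic 488p. When a larger share of cells was required as well, 0 were left in Low.UMI.Pep and Low.UMI.Nonpep. In the Unknown clusters 3 to 14 core genes were lower, with medians at percentiles 46.5 to 73.6 of random lists. Those lists were drawn from the genes given for the same cluster, which had already passed the filters of the deposited values. The percentiles therefore place the core genes among other differing genes, and not among all genes of like abundance. The sizes were small: in Peptidergic 488p the higher core genes ranged from 0.30 for Psma7 to 0.58 for Psmb1 in the authors' deposited table. Psmb5, which codes for the antibody's target, was at 0.69 in Low.UMI.Pep, 0.39 in Peptidergic 488p and 0.30 in Non-peptidergic in the authors' deposited table, and at -1.14 in Unknown 488p, the lowest of any proteasome gene. Psmb5 was detected, by the authors' deposited table, in 79.2% of Peptidergic 488p cells and 68.7% of other cells. When the Unknown clusters were taken out of the reference, the share of Psmb5 in the other neuron clusters, the Low.UMI clusters among them, was 77.7%. Over the 8 core genes for which this could be calculated, 3 were in a larger share of Peptidergic 488p cells and 5 in a smaller one. With the Low.UMI clusters listed for each gene taken out as well, 0 of the 8 were in a larger share. For Psmb7, the only one of these listed for all 3 Low.UMI clusters, the shares were 68.0% in Peptidergic 488p and 98.0% in the other named neuron clusters.

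The 20S core list was called in Low.UMI.Pep alone (Fisher's exact test, adjusted p = 5.26e-06), where 0 of its 8 higher genes were detected in a larger share of cells. A narrower comparison took genes of like abundance that were lower in at least 5 of the 7 Unknown clusters. Of these, 7 of 13 core and 69 of 216 other genes were higher in Low.UMI.Pep (one-sided Fisher's exact test, p = 0.0950). In Peptidergic 488p the adjusted p of the list was 1 and the median of the core genes, 0.39, lay at percentile 70.9 of random lists. At a log2 fold change of at least 0.25 the list was called there (exact test, adjusted p = 0.000404), since its higher members lay between 0.30 and 0.58. The 8 higher core genes of Low.UMI.Nonpep (0.26 to 0.48) and the 7 of SST (0.26 to 0.40) passed that fold change too. The call at 0.25 was therefore not shown to be particular to Peptidergic 488p. In Peptidergic 488p, 7 of 7 higher core genes were detected in a larger share of cells. The same held for all 651 genes higher there, while 952 of the 993 genes higher in Low.UMI.Pep were in a smaller share. This contrast between both clusters is therefore not particular to the core genes. Of 18 measured genes of the 19S cap, which recognises ubiquitin-tagged proteins, 9 were higher in Low.UMI.LTMR, 8 in each of Low.UMI.Nonpep, Low.UMI.Pep and SST, 3 in LTMR, 2 in Peptidergic 488p, 1 in each CGRP cluster and Cold.sen and 0 in Non-peptidergic and Heat.sen. Adjusted over the list alone the count for Peptidergic 488p was 6. The 19S list was called in Low.UMI.Pep (exact test, adjusted p = 0.00585). Both calls in Low.UMI.Pep ended, with an adjusted p of 1, when a gene also had to be detected in a larger share of cells, and likewise at a fold change of at least 1. The immunoproteasome gene Psmb8 had the largest fold change of any proteasome gene, 1.05 in Unknown 488p in the authors' deposited table. Gpm6a and Gpm6b code for neuronal membrane glycoproteins. In the authors' deposited table Gpm6a was highest in Peptidergic 488p (0.62, in 40.7% of cells against 13.1%), and Gpm6b in the satellite-glia-like Unknown.2 (3.74, in 96.9% against 10.4%).

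**Figure D4:**
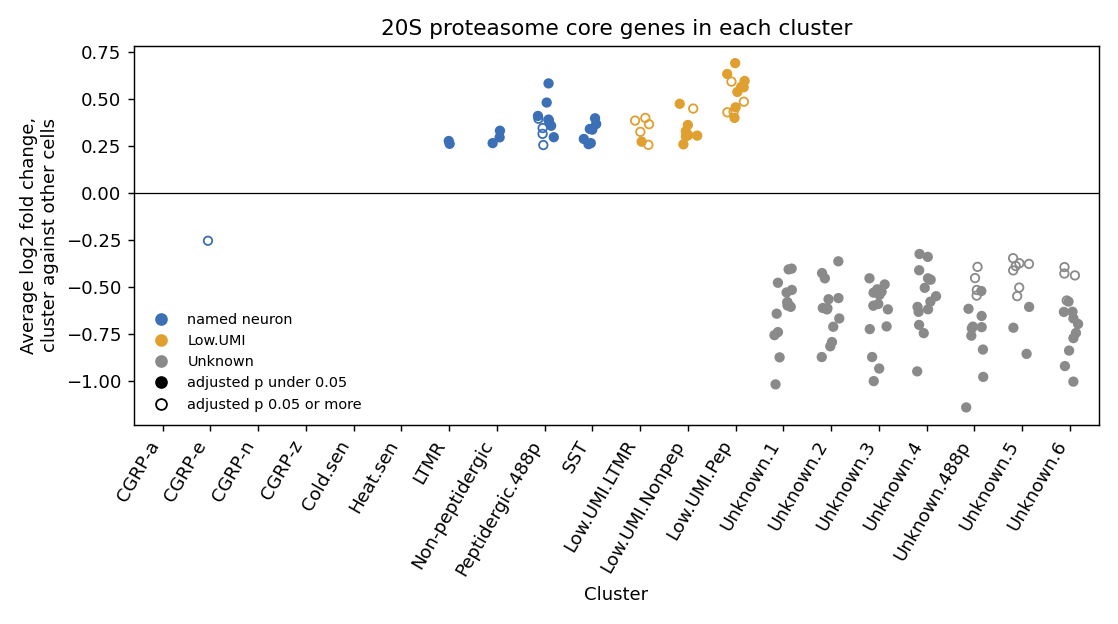
Average log2 fold change (vertical axis) of each 20S proteasome core gene in each cluster (horizontal axis) as listed in the authors' deposited table; filled points have an adjusted p under 0.05, colours mark the kind of cluster name, and points are spread sideways for visibility. Points lie between 0.26 and 0.69 in the neuron clusters with higher core genes and below 0 in all 7 Unknown clusters.

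Over all pairs, 67 of 740 combinations of list and cluster were called, 30 for cell types and 37 for functions. For 53 of the 67 the number of higher members did not change when adjusted over the list alone, and for 14 it grew. Another 8 lists were called in no cluster: those of Mrgprb4 touch neurons, neutrophils, lymphocytes, erythroid cells, the immunoproteasome, proteasome activators and assembly factors, GPM6 proteins and the response to axon injury. The erythroid and lymphocyte lists had only Hbb-bs and only Cd79a measured, too few for any call. Of the neutrophil list 3 of 3 measured genes were higher in Unknown 488p, with S100a8 at 6.15 in 13.0% and S100a9 at 6.61 in 11.6% of its cells in the authors' deposited table. All 3 were below the 25% of cells that the exact test required, so that list could not be called there.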

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

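No paired analysis was possible because the table gives values per cluster and none per sample, and for the same reason no replicate was left out. The only added alternative, that the share of cells differ in the direction of the fold change, was chosen after seeing the data. The depth per cell is unknown, which limits any comparison of shares between clusters. Cluster shares moved by at most 0.00371 percentage points under the stricter gene filter or the robust solution. Ranked by the difference of shares, 22 of 59 leading genes were kept.

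The numbers of genes changed by more than 1.5 times under several settings, which follows from their stricter thresholds. At an absolute log2 fold change of at least 1, 3641 of 19614 higher and 4279 of 29433 lower calls were left over the 20 clusters, 70 of 651 and 165 of 1270 in Peptidergic 488p, and 464 of 915 and 540 of 3042 in Unknown 488p. At an adjusted p under 1e-10, 19606 lower calls were left over all clusters, 324 higher and 244 lower in Peptidergic 488p, and 1423 lower in Unknown 488p. Of the 20S core genes, 1 in Peptidergic 488p, 3 in Low.UMI.Nonpep and 0 in Low.UMI.Pep then remained higher, and of the 19S genes in Peptidergic 488p 0. With the condition on shares, 0 core genes were higher in Low.UMI.Nonpep and Low.UMI.Pep. For the other 18 clusters, 12 of the 36 counts of higher or lower genes moved by over 1.5 times under that condition.

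Against the genes listed for the cluster itself, 35 list calls were made in place of 67. At a fold change of at least 1, 29 of the 67 were lost, and at 0.25, 13. Other pairs were newly called: the totals were 45 calls at 1, with 38 of the 67 kept, and 73 at 0.25, with 54 kept. Of the losses at 0.25 only the neuropeptide call in CGRP-a and the Mrgpra3 call in Peptidergic 488p are named here. In Peptidergic 488p the adjusted p became 0.0977 for the Mrgprd list, 0.109 for the Mrgpra3 list and 0.0526 for the neuronal list, and in Unknown 488p 0.270 for the ubiquitin list. At a fold change of at least 0.25 the Mrgpra3 list reached 0.0547 and the 20S core list in Peptidergic 488p passed the threshold (0.000404). At a fold change of at least 1 the ubiquitin list in Unknown 488p was at 0.832 and the 20S list in Low.UMI.Pep at 1, and with no minimum share the former was at 0.0756. The condition on shares also gave 1 for the 20S list in Low.UMI.Pep. At a fold change of at least 1 the shared genes fell to 26.4% for CGRP-e and CGRP-n, 16.2% for Low.UMI.Nonpep and Peptidergic 488p, and 6.92% for Unknown.1 and Unknown 488p. The cause of these changes was not tested beyond the number of genes left.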

Other observations

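Genes of the immediate early and heat shock response, which dissociation of tissue is known to induce, were higher in most non-neuronal clusters. The list was called in 5 of the 7 Unknown clusters and in no neuron cluster: Unknown.1 with 11 of 14 genes higher (Fisher's exact test, adjusted p = 2.01e-05), Unknown.2 with 10 (7.74e-07), Unknown.3 with 10 (2.83e-08), Unknown.6 with 7 (6.59e-05) and Unknown.4 with 4 higher and 3 lower (0.0105, lost at a log2 fold change of at least 1 with 0.0616). In the authors' deposited table Egr1 was at 2.15 and Fos at 2.07 in Unknown.2. In Peptidergic 488p, 10 of the 14 genes were lower, the median of -1.47 lay below those of all 10000 random lists, and the authors' deposited table gave -2.91 for Fos and -2.61 for Egr1. This was not particular to that cluster, as 12, 13 and 12 of the genes were lower in Low.UMI.LTMR, Low.UMI.Nonpep and Low.UMI.Pep and 7 in LTMR. The macrophage-like Unknown 488p and the fibroblast-like Unknown.5 each had 2 members higher and 4 lower. The axon injury list was called nowhere, and its growth-related member Gap43 was at 1.51 in Low.UMI.Pep, 1.15 in Peptidergic 488p and between 1.01 and 1.42 in the 4 CGRP clusters in the authors' deposited table.

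Detection of the nuclear long non-coding RNA Malat1 also varied between clusters. In the authors' deposited table it was detected in 27.4% of Low.UMI.LTMR, 37.8% of Low.UMI.Pep, 42.7% of Low.UMI.Nonpep and 44.6% of Peptidergic 488p cells. It was found in 94.1% of SST cells at -2.49, and in 97.3 to 100% of the cells of each Unknown cluster listing it, in the authors' deposited table.

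Of the tests below, the comparison of 20S core genes with other genes was set before its result was seen, and the tests of depth, of the library and of Fc receptors were chosen after the values they rest on had been seen. The depth test of the core genes was the last of 4 forms tried, and the earlier ones, which counted genes with a larger share against 3 different references (7 of 7, 3 of 8 and 0 of 8), decided nothing because the reference or the cluster fixed their outcome.

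Core proteasome genes were higher in Peptidergic 488p, with 7 of 14 higher and 0 lower. Low depth of the cells stays open: with the Low.UMI clusters listed for each gene taken out of the other neuron clusters, 0 of 8 core genes and 17 of 105 other genes of like abundance were in a larger share of Peptidergic 488p cells (two-sided Fisher's exact test, p = 0.604). A reference that holds many non-neuronal cells stays open too. Among the genes lower in at least 5 of the 7 Unknown clusters, 7 of 13 core genes and 105 of 216 other genes of like abundance (48.6%) were higher in Peptidergic 488p (one-sided Fisher's exact test, p = 0.467), so the pattern may reflect neurons set against non-neurons, although this p does not show that both rates were equal. The same comparison was not predicted for other clusters. Its smallest p over the 13 neuron clusters was in Low.UMI.Nonpep (8 of 13 against 81 of 216, one-sided Fisher's exact test, p = 0.0774). Core genes were higher less often than the other genes in LTMR (2 of 13 against 99 of 216) and Non-peptidergic (3 of 13 against 92 of 216). In CGRP-n 0 of 13 core and 59 of 216 other genes were higher. A link to the sorted population was not tested, since the table does not give the population of a cell.

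Of 20 glial list genes, 10 were lower in both SST and Peptidergic 488p, 8 of them with a smaller share of cells in both than over all cells, and of the 10 genes 9, 10 and 10 were also lower in Low.UMI.LTMR, Low.UMI.Nonpep and Low.UMI.Pep. In the authors' deposited table Sparc was in 1.7% and 1.3% of their cells but in 15.8% of CGRP-n and 24.0% of Non-peptidergic cells, whereas Glul was in 92.8% of SST and Ptprz1 in 31.6% of Peptidergic 488p cells and Cdh19 was rare in Non-peptidergic (1.5%) and LTMR (1.9%) too. Shares and fold changes did not give the same contrast. Apoe was at -5.88 in both SST and Peptidergic 488p in the authors' deposited table. It was at -5.56 in Non-peptidergic, -5.17 in LTMR and -3.46 in CGRP-a, where it did not pass the adjusted p filter. For depth, the genes detected in 40 to 60% of all cells were used where listed for the cluster, having passed the filters of the deposited values. In SST, 871 such genes were more frequent than in the other cells by a median of 45.3 percentage points. This argues against a depth in SST as low as that of the Low.UMI clusters. The other cells include the Low.UMI and Unknown clusters, so a depth in SST below that of other named neuron clusters stays open. In Peptidergic 488p the 1236 listed genes detected in 40 to 60% of all cells had a median difference of -12.0 percentage points. Low depth may therefore account for the pattern there, at least in part. A library with less free RNA than the one that gave the other named neuron clusters is a candidate explanation that cannot be told apart from a difference between the cell types, because no cell is assigned to a library.

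The macrophage-like Unknown 488p carries the same suffix as Peptidergic 488p. If the suffix marks labelled cells, antibody bound through Fc receptors could have brought macrophages into the sort: 3 Fc gamma receptor genes were higher in Unknown 488p, with Fcgr3 in 69.9%, Fcgr2b in 47.3% and Fcgr1 in 34.9% of its cells in the authors' deposited table. The table holds no control without primary antibody, so this stays open for Unknown 488p. For Peptidergic 488p the shares in other cells allow Fcgr3 transcripts in at most 8.35% of its cells, but this bounds detected transcripts and not the receptor, so the same route stays open there. No biological explanation was tested for any of these patterns.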
